A study of Mus musculus with 6 samples.

How the data were processed

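RNA was measured in regulatory T cells (Treg), the Foxp3-expressing T cells that restrain immune responses, sorted as YFP-positive CD4 cells from mouse spleen. Per the labels, 3 libraries came from KAP1 sufficient and 3 from KAP1 deficient cells, and libraries were made with a TruSeq kit. KAP1, also called TRIM28, is a co-repressor that KRAB zinc finger proteins bring to DNA. Groups and replicate numbers were taken from the sample titles. The labels do not say which samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

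Per the submitters' processing notes, TopHat2 2.1.1, HTSeq 0.7.2, DESeq2 and the mm10 build were used, with no role or order given. The annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, and of genes with near-identical copies, cannot be assigned with certainty. The deposited table holds raw counts per Ensembl gene, whole numbers without normalization, for 37991 genes. A second table deposited by the authors holds their own comparison: per the file headers, a mean level, a log2 fold change with its standard error, a test score, and p-values with adjusted p-values and q-values. How the q-value differs from the adjusted p is not given in the sources used here. Its log2 fold changes, deposited by the authors, are positive where sufficient cells were higher. Gene names came from a reference table that matched 32919 of the gene identifiers, and the 5072 rows without a name held 0.603% of all counts. Gene positions are from GENCODE M21 on the same assembly, which had a position for 32938 rows. Of the 24421 rows in the authors' deposited table, 21378 were matched to the counts.

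Totals ran from 9954344 to 10994745 counts per library, so 3 counts, taken as the limit that a count of 0 allows, correspond to 0.273 to 0.301 CPM, the count scaled by the library total without TMM factors. Intervals and floors cover counting error only. The 6 libraries were compared in pairs by a chi-square test over genes, and the smallest chi-square per degree of freedom was 2.54, above sampling noise, so none was treated as a duplicate.

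Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersion, TMM factors and filterByExpr, and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the fold change and the test's F value. Positive values mean higher in the deficient group. Gene lists, 36 in number with 878 entries, were fixed before the data were examined. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, then with an estimated correlation and with fry. DESeq2 1.42.0 and limma-voom served as alternatives, beside other scaling factors, filters, a replicate block, a fold limit of 1.5, a non-robust fit and leaving out each library. Tables used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

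Genes were named by a rule fixed in advance: Trim28; Foxp3, Il2ra, Ctla4, Tnfrsf18, Ikzf2, Slc1a5 and Mki67; the 10 largest called changes per direction at a mean log2 CPM of at least 1, with no overlap between groups, leaving out predicted genes, receptor segments and pseudogenes; and up to 4 called members per list, or the 2 with the smallest adjusted p where a list on biology had none. Because Trim28 went against the label in 2 libraries, the same fits were also run on the other 4 libraries, replicates 1 and 2 of each group. That choice was made after seeing the data, and the naming rule was applied to both fits. Some genes that the rule names are not reported here. The fits were tested on simulated data. With all 6 libraries and 12158 genes, 70% of genes given a 2-fold change were recovered, and 14% at 1.25-fold. Every simulated library carried the change of its label, whereas Trim28 goes against the label in 2 real libraries. The shares for 6 libraries therefore do not say what the labelled fit could find in these data. With the 4 libraries and 12183 genes, 82% were recovered at 2-fold and 50% at 1.25-fold.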

Results

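Transcripts were counted in 6 libraries of splenic Treg, 3 labelled KAP1 sufficient and 3 labelled KAP1 deficient. Each library held 9954344 to 10994745 counts. The comparison asks which transcripts differ when Treg lack KAP1.

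Trim28, the gene that encodes KAP1 (ENSMUSG00000005566, chromosome 7, 12999114 to 13031035, mm10), went against the label in 2 libraries. The libraries labelled sufficient replicates 1, 2 and 3 held 2462, 2483 and 218 Trim28 counts, and those labelled deficient replicates 1, 2 and 3 held 232, 185 and 2544. The library labelled sufficient replicate 3 thus stood at 8.68% of the mean of sufficient replicates 1 and 2, and the library labelled deficient replicate 3 at 94.9%. Under the labels Trim28 averaged 170 ± 129 CPM in the sufficient group and 91.0 ± 122 CPM in the deficient group (SD, n = 3 each), a log2 fold change of -0.90 ± 1.46 (SE) with an edgeR adjusted p of 0.889. Every direction given for all 6 libraries below rests on labels that Trim28 contradicts in 2 of them.

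**Figure D1:**
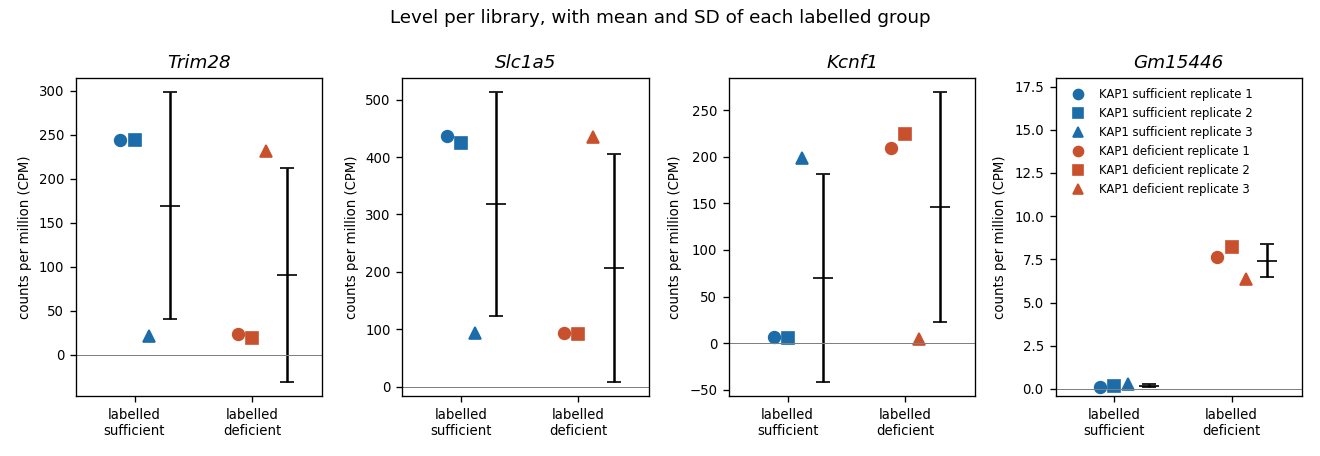
CPM values of Trim28, Slc1a5, Kcnf1 and Gm15446 in each library (y axes, linear, each with its own scale), by labelled group (x axis), with the mean and SD of each labelled group in black (n = 3). Trim28, Slc1a5 and Kcnf1 in both libraries labelled replicate 3 lie at the level of the opposite group, while Gm15446 lies at 0.291 CPM or less in the 3 libraries labelled sufficient and at 6.37 CPM or more in the 3 labelled deficient.

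With all 6 libraries as labelled, 2 genes of 12158 tested changed, 1 in each direction. Gm15446, a predicted gene (ENSMUSG00000090015, chromosome 5, 109923400 to 109943936), was higher in the group labelled deficient, at 7.41 ± 0.955 against 0.196 ± 0.0960 CPM (SD, n = 3 each). Its log2 fold change was 5.15 ± 0.33 (SE, edgeR adjusted p = 0.000495), and it was named after its values were seen, because the naming rule leaves out predicted genes. Mir142hg, the host transcript of the microRNA miR-142 (chromosome 11, 87755577 to 87757270), was lower, at 16.7 ± 0.501 against 38.6 ± 6.89 CPM, a log2 fold change of -1.22 ± 0.13 (edgeR adjusted p = 0.0246). Mir142hg lost its call, at log2 fold changes of -1.12 to -1.23, with limma-voom, the replicate block, a fold limit of 1.5, the non-robust fit and without any single library other than the one labelled sufficient replicate 3, and Gm15446 lost its call with the replicate block at an unchanged log2 fold change of 5.15. At an unadjusted p under 0.05 there were 944 genes. Without the library labelled sufficient replicate 3, 807 genes were called, and with both doubted libraries left out 2114 were.

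None of the genes fixed in advance passed the edgeR test under the labels, where the calls were 2 genes, and 944 at an unadjusted p under 0.05. Foxp3, the lineage factor of Treg, had a log2 fold change of -0.18 ± 0.07, Ikzf2 0.22 ± 0.07, Il2ra 0.01 ± 0.06, Ctla4 -0.03 ± 0.08, Tnfrsf18 0.05 ± 0.06, Slc1a5 -0.63 ± 0.99 and Mki67 -0.37 ± 0.30 (SE). The Slc1a5 value was -1.775 without the library labelled deficient replicate 3 and -0.268 without deficient replicate 2. Of the 25 lists tested, ribosomal protein genes were called higher (camera adjusted p = 0.000174), and cell cycle genes (0.00038), cholesterol synthesis genes (0.007) and helper cytokine genes (0.0227) lower. None of the 4 was called with an estimated correlation, where each adjusted p = 0.853. No member of these lists was called over all genes, and adjusted over the list alone 8 ribosomal protein genes rose and 1 fell, and 1 helper cytokine gene fell. Ribosomal protein genes share reads with processed pseudogenes, so their values are uncertain. In the 4 libraries without the 2 doubted ones this list was not called (camera adjusted p = 0.0578), with 11 members higher and 4 lower.

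In the 4 libraries in which Trim28 goes with the label, 2114 of 12183 tested genes were called, 1214 higher and 900 lower in deficient cells, with 2 libraries per group. With upper-quartile factors the split was 1046 higher and 1248 lower. Trim28 itself, by which these libraries were chosen, fell by 3.54 ± 0.08 on the log2 scale (edgeR adjusted p = 2.74e-13). Changes of at least 2-fold were found for 187 genes that rose and 98 that fell, and of at least 8-fold for 40 and 5. DESeq2's Wald test with its own filter called 935 genes in the 4 libraries and kept 44.0% of the 2114. All 6 libraries grouped by Trim28 level gave 1000 calls by edgeR, fewer than the 2114 although each group held 1 library more. The spread between only 2 libraries per group may therefore be too small, and the SEs of the 4-library fit with it.

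Of the 1214 genes that rose, 70 (5.77%) had a mean under 1 CPM in sufficient replicates 1 and 2. Of the 900 that fell, 30 (3.33%) had a mean under 1 CPM in deficient replicates 1 and 2. Myo5b, a myosin motor of vesicle transport (chromosome 18, 74440936 to 74771493), had 1 count over sufficient replicates 1 and 2 and 1824 and 1446 counts in deficient replicates 1 and 2, a ratio of 3310 with a 95% exact binomial counting interval of 594 to 131000. Its fitted log2 fold change of 11.37 became 10.54 without sufficient replicate 1 and 13.68 without sufficient replicate 2. The potassium channel subunit gene Kcnf1 (chromosome 12, 17172100 to 17176888) rose by 5.23 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 3.84e-14). Cacna1b, a calcium channel subunit gene, rose by 6.50 ± 0.31, the lipid transporter gene Abca5 by 4.61 ± 0.17, the kinase gene Yes1 by 4.61 ± 0.28, and the vomeronasal receptor gene Vmn2r96 by 4.31 ± 0.19. Slc1a4, a neutral amino acid transporter gene, had a log2 fold change of 4.14 ± 0.26 (4.80 without sufficient replicate 1), Spats2 of 4.09 ± 0.30 and Ceacam16 of 3.36 ± 0.32. Ly6d (4.97 ± 0.55) lost its call without sufficient replicate 1 (6.20) or 2 (4.30).

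Among the genes that fell, the lectin-like receptor gene Klrg1 had a log2 fold change of -4.09 ± 0.35 (-5.07 without deficient replicate 2) and the adhesion gene Bcam of -4.04 ± 0.25. Slc1a5, a glutamine transporter gene (chromosome 7, 16781340 to 16798274), fell by 2.21 ± 0.06 on the log2 scale (edgeR adjusted p = 8.83e-13). Hdac9 (-2.17 ± 0.28), Ccdc61 (-2.02 ± 0.14), Pcyt1b (-1.78 ± 0.27), Arnt2 (-1.77 ± 0.32) and Nav2 (-1.72 ± 0.10) also fell. The proliferation marker Mki67 had a log2 fold change of -0.77 ± 0.08. Foxp3 (-0.25 ± 0.05, adjusted p = 0.00509) and Ikzf2 (0.19 ± 0.05, adjusted p = 0.0167) passed, and Il2ra (0.07 ± 0.05), Ctla4 (-0.08 ± 0.08) and Tnfrsf18 (0.13 ± 0.05) did not. Neither Foxp3 nor Ikzf2 passed in the authors' deposited table, with adjusted p-values there of 0.205 and 0.944. The library labelled deficient replicate 3, where Trim28 is high, held Foxp3 at 612 and Ikzf2 at 1135 CPM. Deficient replicates 1 and 2 averaged 605 and 986 CPM. Ikzf2 lost its call without sufficient replicate 2 (0.18) or deficient replicate 1 (0.17), and Ctla4 gained one without sufficient replicate 1 (-0.21).

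Of 38 tested cell cycle genes 23 fell, none rose and 15 did not pass in the 4 libraries, with 33 lower adjusted over the list alone and a median log2 fold change of -0.50. Camera called the list lower (adjusted p = 1.08e-11), and with an estimated correlation it was not called (adjusted p = 0.648). Examples were Aurkb (-1.05 ± 0.17), Rrm2 (-0.62 ± 0.09) and Rrm1 (-0.46 ± 0.08). Genes of effector Treg fell in 11 of 24 cases and rose in 1, adjusted over the list alone 13 and 1, among them Maf (-0.60 ± 0.06) and the costimulatory receptor gene Icos (-0.60 ± 0.07). Of 12 helper cytokine and lineage genes 6 fell (8 adjusted over the list alone), including Tbx21 (-0.90 ± 0.22), Ifng (-1.58 ± 0.37) and Tnf (-0.44 ± 0.09). Camera adjusted p-values were 0.000796 for effector Treg and 0.000599 for helper cytokine genes, and each adjusted p = 0.648 with an estimated correlation. Other cells' markers that fell in the same 4 libraries were Cd22 (-1.18 ± 0.22), Igkc (-2.55 ± 0.57) and Ighm of the B cell list, Cd74 (-0.42 ± 0.09) of the dendritic list, Ctss of the myeloid list and Nkg7 (-0.48 ± 0.14) of the CD8 T cell list.

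Of 147 tested KRAB zinc finger genes, whose proteins bind KAP1, 26 rose, 2 fell and 119 did not pass in the 4 libraries, with 27 and 2 adjusted over the list alone and a median log2 fold change of 0.11 (camera adjusted p = 0.00135; adjusted p = 0.648 with an estimated correlation). The members with the smallest adjusted p were Zfp53 (1.88 ± 0.05), Zfp52 (1.55 ± 0.08) and Zfp948 (1.94 ± 0.10) on chromosome 17, and Zfp445 (0.35 ± 0.06), while Zfp51 on chromosome 17 fell (-0.28 ± 0.08). Of 22 genes for KAP1 partners 7 rose and 3 fell, 8 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0915). Those that rose included Trim24 (2.15 ± 0.12), the histone methyltransferase gene Setdb1 (1.29 ± 0.05) and Morc3 (1.16 ± 0.06).

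Interferon-stimulated, trafficking, co-inhibitory and cholesterol synthesis genes were also called lower by camera (adjusted p = 0.0205, 0.0369, 0.0369 and 0.0473), and none with an estimated correlation (adjusted p = 0.648, 0.648, 0.648 and 0.68). Interferon-stimulated genes moved both ways, with 8 falling, such as Ifit3 (-0.93 ± 0.15) and Ifit1 (-0.59 ± 0.08), and 3 rising, such as Usp18 (0.97 ± 0.07), of 32 (9 and 3 adjusted over the list alone). Trafficking genes fell in 9 of 21 cases, including Gpr15 (-0.98 ± 0.22) and Itgb1 (-0.46 ± 0.06), and rose in 1 (10 and 3 adjusted over the list alone). Of 11 co-inhibitory genes 4 fell, including Pdcd1 (-0.34 ± 0.08), and Btla rose (0.93 ± 0.05), with 6 and 1 adjusted over the list alone. Of 21 cholesterol genes 3 fell, including Mvk (-0.49 ± 0.15), and Mvd rose (0.51 ± 0.10), with the same numbers adjusted over the list alone. Mvk stood at 9.095 CPM in deficient replicate 3, where Trim28 is high, and averaged 9.233 CPM in deficient replicates 1 and 2. The adjusted p of Mvk in the authors' deposited table was 0.313. Fry, which tests whether a list's genes move one way without comparing them with other genes, gave adjusted p-values in the 4 libraries of 0.0493 for KRAB zinc finger genes (higher) and for amino acid and ATF4 genes (lower, with a median log2 fold change of -0.05 but a mean of 0.03), 0.0501 for helper cytokine genes and 0.125 for cell cycle, effector Treg and trafficking genes. With all 6 libraries no list passed fry's directional test, the lowest adjusted p being 0.316 for ribosomal protein genes.

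Several markers of other cells were near the floor, and others were not. Cd8a had 0 to 5 counts and Lyz2 0 to 4 per library, while Cd4 had 8380 to 10055. Ighm, an antibody heavy chain gene, had 5303 to 6810 counts per library and made up 95.9% of the counts of the B cell list, the protease gene Ctss had 2607 to 3465 and made up 97.5% of the myeloid list, and the adhesion gene Pecam1 had 2045 to 2503 and made up 99.2% of the stromal list. In the 4 libraries Ighm (-0.27 ± 0.05) and Ctss (-0.34 ± 0.05) fell, and Klrb1c of the natural killer list rose (1.94 ± 0.22). Igkc, an antibody light chain gene, had 14, 41 and 10 counts in the libraries labelled sufficient and 5, 4 and 40 in those labelled deficient. The mitochondrial share of counts was 1.92%, 2.1% and 1.41% in the libraries labelled sufficient and 1.34%, 1.33% and 1.61% in those labelled deficient. Immediate early genes, which respond to cell handling, were lower in 8 of 20 cases and higher in 2 in the 4 libraries (camera adjusted p = 0.0915), such as Egr1 (-0.75 ± 0.06).

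**Figure D2:**
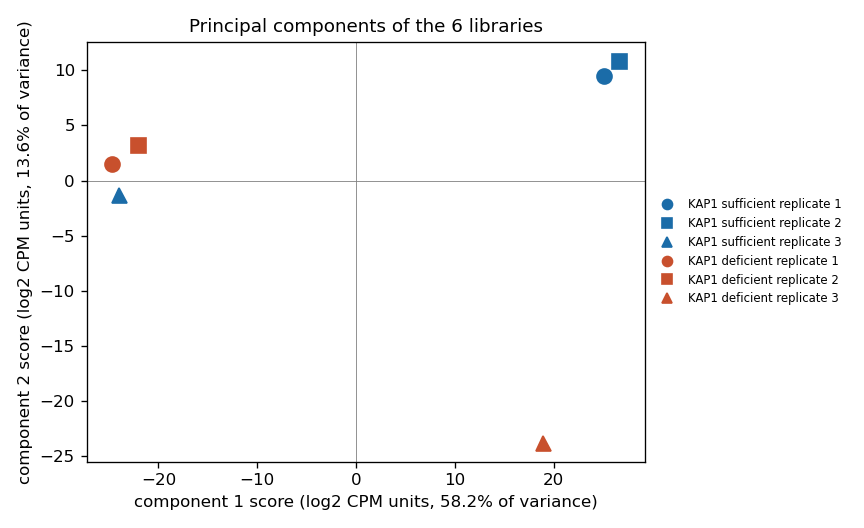
Scores of the 6 libraries on the first principal components of log2 CPM (x axis, component 1, 58.2% of variance; y axis, component 2, 13.6%), with colours for the labelled group and shapes for the replicate. On component 1 the library labelled deficient replicate 3 lies at 18.9, near sufficient replicates 1 and 2 at 25.1 and 26.6, and the library labelled sufficient replicate 3 at -24.0, near deficient replicates 1 and 2 at -24.7 and -22.0. On component 2 the library labelled deficient replicate 3 lies apart from the others, at -23.8.

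The authors' deposited table calls 829 genes at an adjusted p under 0.05, 465 higher and 364 lower in deficient cells. In the authors' deposited table, where positive values mean higher in sufficient cells, the log2 fold change was 3.11 for Trim28, 2.14 for Slc1a5, -4.34 for Kcnf1 and -0.07 for Gm15446. None of the 774 genes that the authors' deposited table calls among 10677 shared with the fit of all 6 libraries was called there, where 1 of the shared genes was called by edgeR. Of the 775 it calls among 10696 shared with the 4-library fit, 702 were called there too, against 135.9 in either direction for independent lists, and 701 of them had the same direction. Both rest on the same libraries, so the overlap is not independent evidence.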

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

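The fits on 4 libraries were chosen after seeing the data; the other alternatives were set before the data were examined. With all 6 libraries, the 2 called genes became 6 with DESeq2's Wald test and its own filter, which tested 18640 genes in place of 12158, and 1 with limma-voom, with a fold limit of 1.5 or with the non-robust fit. The replicate block gave 0 calls by edgeR, with 705 genes at an unadjusted p under 0.05; same-numbered libraries had deviations correlated at -0.373, -0.307 and -0.617, but both doubted libraries bear the number 3, which shapes these values, so they do not show whether the numbers pair samples. Leaving out single libraries gave 1 to 807 calls, the highest without the library labelled sufficient replicate 3, and 1 to 9 called lists in place of 4, lowest without sufficient replicate 2 and highest without sufficient replicate 3. With an estimated correlation 0 lists were called. For glycolysis genes the unadjusted camera p went from 0.0225 to 0.0699 although their estimated correlation, -0.00801, lay below the preset 0.01. Fewer calls under that setting therefore do not by themselves show that correlation between genes made the calls. Leaving out both doubted libraries gave 2114 genes, 8 lists, a Trim28 log2 fold change of -3.54 and 701 genes shared with the authors' deposited table in place of 0.

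On the 4 libraries, the 2114 calls became 935 with DESeq2's Wald test and its own filter (17899 genes tested in place of 12183) and 180 with a fold limit of 1.5, which tests larger changes; the replicate block gave 2359. Leaving out single libraries gave 1632 to 1717, with the lone library assumed to vary like the other group, and 67.1% to 69.8% of the 2114 genes remained called. Called lists went from 8 to 0 with an estimated correlation and to 5 to 8 without single libraries, lowest without sufficient replicate 2. The cause was not tested where none is named. For 25 named genes, 311 of 319 values stayed on their side of the threshold, 7 lost the call, 1 gained it and 0 called values reversed; over both fits, 6 of all 491 values of single genes changed sign, none of them called. With all 6 libraries 128 of 144 values for 9 genes stayed, 10 lost the call and 6 gained it, among them Foxp3 (-0.25) and Ikzf2 (0.25) without sufficient replicate 3. Depth limits genes below 0.273 to 0.301 CPM, the level of 3 counts.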

Other observations

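The tests in this part were chosen after the results were seen, except the edgeR fit of all 6 libraries, which was planned, and the test without zinc finger genes and both tests on neighbouring genes, whose bounds were written before. Genes of TGF-beta signalling were not called as a list in the 4 libraries (camera adjusted p = 0.313), but 6 of 16 rose, including Skil (0.48 ± 0.05), Smad7 (0.31 ± 0.06) and Tgfb3 (1.33 ± 0.36, named after its values were seen), and 2 fell, including Smad2 (-0.33 ± 0.07). Of 19 apoptosis genes 1 rose, the survival gene Bcl2 (0.52 ± 0.05), 2 fell, including the pro-apoptotic gene Bbc3 (-0.52 ± 0.11), and 16 did not pass (camera adjusted p = 0.165). Among 22 amino acid transport and ATF4 target genes 2 rose and 4 fell, with the neutral amino acid transporters Slc1a4 and Slc1a5 moving apart. The heat shock gene Hspa1b, named after its values were seen, followed the labels in all 6 libraries, with 11, 12 and 5 counts in those labelled sufficient and 59, 59 and 139 in those labelled deficient, and did not pass the edgeR test there (adjusted p = 0.219), but did in the 4 libraries (2.37 ± 0.29, adjusted p = 4.41e-05). It shares reads with a near-identical paralog, so its counts are uncertain.

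Trim28 goes against the label in 2 libraries, and on component 1 both lie with the group of the opposite label. The smallest chi-square per degree of freedom, 2.54, was that of sufficient replicate 3 with deficient replicate 1. Sufficient replicate 3 had 12.3 and 14.4 with sufficient replicates 1 and 2. Deficient replicate 3 had 7.7 and 8.2 with sufficient replicates 1 and 2, and 9.3 and 9.2 with deficient replicates 1 and 2. By Trim28 level both doubted libraries thus stand opposite to their labels. An exchange of the labels of these 2 libraries is a candidate explanation that stays open. Of 2113 genes called in the other 4 libraries, 71.9% differed between the doubted libraries opposite to the labels, and 87.7% of the 284 with at least a 2-fold change did. The first share fell short of a bound of 75% that was written after the data were seen, so it decides nothing. Relative to deficient replicates 1 and 2, 28 genes raised at least 16-fold in the 4 libraries stood at a median of 99.0% in the library labelled sufficient replicate 3. Their median was 2.47% in sufficient replicates 1 and 2. Incomplete deletion in deficient replicate 3 alone leaves unexplained the Trim28 level of sufficient replicate 3, at 8.68% of its group's other libraries. That level was part of the pattern first seen, so it does not test deletion in deficient replicate 3. Mixed RNA in deficient replicate 3 is argued against by a median of 1.86% there for the same 28 genes. The fold changes of the authors' deposited table correlated across genes at -0.81 with the arrangement that exchanges the 2 libraries and at -0.53 with the labelled one. The authors' fold changes have the opposite sign, so a negative value means agreement, and genes are not independent replicates. Their table gave Trim28 3.11 ± 0.08 (SE) and called 829 genes. The labelled arrangement gave -0.90 ± 1.46, and 6 calls with DESeq2's Wald test. These values argue against a comparison of the 6 libraries by their column names. Gm15446 and Mir142hg, called by the planned test over all genes, follow the labels in all 6 libraries. They were picked because they differ between the labelled groups, so this weighs neither for nor against an exchange, and 2 other splits also called 1 gene each. Whether columns, tubes or animals differ from their labels was not tested.

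The 6 libraries make 10 splits, too few for a share under 0.05. The labelled split called 2 genes, and 2 of the 10 splits, the labelled one included, gave as many, with 1000 the highest of the others. It called 4 lists, and 5 of the 10 splits, the labelled one included, gave as many, with 11 the highest of the others. The split with 1000 genes, which sets sufficient replicates 1 and 2 and deficient replicate 3 against the rest, points to a structure of the samples other than the labels.

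Lowered genes were frequent near Trim28 in the 4 libraries, with an odds ratio of 6.58 for a fall of at least 2-fold within 10 Mb (2-sided Fisher's exact p = 5.00e-04) and of 2.13 for a rise (Fisher's exact p = 0.128). In both directions together, 10 of 131 tested genes there changed at least 2-fold, among them Slc1a5, Bcam, Ccdc61 and Ceacam16, against 256 of 11731 elsewhere (odds ratio 3.70, Fisher's exact p = 7.24e-04). A segment of chromosome that travels with the engineered allele may account for this, and an effect of KAP1 on nearby genes was not told apart from it. The excess did not rest on zinc finger genes themselves, since without them 9 of 103 genes there changed (odds ratio 4.26, Fisher's exact p = 5.18e-04). An effect of zinc finger gene clusters on neighbouring genes was not tested. The share did not fall steadily with distance, which weakens the pattern. It was 4.65% up to 5 Mb, 9.09% from 5 to 10 Mb, 1.96% from 10 to 20 Mb, 5.34% from 20 to 40 Mb and 1.66% farther along the chromosome. The first 20 Mb of chromosome 7, with 10 of 131 genes, ranked 3 of 186 such windows, which overlapped. Windows ranked 1 and 2 held 5 of 55 and 4 of 52 genes, so shares as high also occurred elsewhere, on fewer genes. Neighbouring genes are not independent.

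Called genes of the same direction lay next to each other more often than after shuffling. In the 4 libraries 204 neighbouring pairs were both raised, against at most 151 in 1000 shuffles within 10 classes of expression level, which argues against expression level as the whole cause. Without pairs within 5 kb, 165 remained against at most 108, which argues against reads shared between genes within 5 kb as the whole cause. Reads shared over longer distances, or between related copies farther apart, were not tested. Lowered genes did so too, with 111 pairs against at most 102, and 77 against at most 75 without pairs within 5 kb. No biological explanation was tested.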
